A study of Mus musculus with 2 samples.

How the data were processed

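Total RNA from the livers of mouse embryos at embryonic day 12.5 was sequenced in 2 libraries that form 1 group. Per the labels, replicate 1 came from a pool of 120 embryos and replicate 2 from a separate pool of 88 embryos of the B6NCrl strain, each with both sexes mixed. Per the labels' protocols, RNA was extracted with the Ambion mirVana kit, each library started from 10 ng of RNA with a size range above 200, control spike-ins were used, and the manual of a SMARTer low-input kit is linked. The labels give no strandedness, so genes that overlap on opposite strands could not be told apart with certainty.

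The authors deposited, for each library, 1 table of genes and 1 table of transcripts, quantified on assembly mm10 with GENCODE annotation M4 per the header texts deposited with each library. The aligner and quantifier and their versions are not given in the sources used here. The tables were made from each library alone. The expected counts are estimated reads per gene or transcript made by the authors, not normalized, and they need not be whole numbers because reads that match several transcripts were shared among them. The deposited TPM values are length-scaled transcript abundances that sum to a fixed total over all entries of a table, spike-ins included, and the deposited FPKM values are counts scaled by effective length and depth. The percent of a gene's TPM held by each transcript is also a column made by the authors, per the file headers, and the shares given here were recomputed from the transcript TPM. The effective length equals the length minus 99 for every entry longer than that and is 0 otherwise, so that a few reads give a very large TPM to a gene just above that length. The deposited confidence bounds of TPM were not used.

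The gene tables held 69691 entries, of which 43346 were mouse gene identifiers, 26248 were tRNA entries and 97 were spike-ins, 96 of them of the ERCC set. Symbols were matched by unversioned gene identifier for 42462 identifiers. The remaining 884 identifiers held 0.218% of the expected counts in replicate 1 and 0.217% in replicate 2. Gene classes, transcript types and coordinates came from the GENCODE M21 annotation, which uses the same mm10 assembly as the deposited tables. Coordinates are 1-based.

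The libraries held 37.6 M expected counts in replicate 1 and 34.7 M in replicate 2, of which spike-ins took 2.94% and 3.19%. For a gene with an effective length of 1 kb, a floor of 3 reads corresponded to 0.0953 TPM in replicate 1 and 0.103 TPM in replicate 2. Intervals of ratios between the libraries were exact 95% Clopper-Pearson intervals from the expected counts rounded to whole numbers. PCR reads without molecular identifiers are not independent molecules, so these intervals and the floors cover counting error only.

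The design has 1 group, so no comparison between conditions was possible and no p-value was computed. Agreement of the replicates was described by Pearson's r and Spearman's rho across genes of log2(TPM + 1), with an interval from 200 bootstrap draws over genes, which are not independent replicates. It was also described by the common biological coefficient of variation from edgeR 4.0.16 in R 4.3.3 on rounded expected counts with TMM normalization, the tool's default filter on low counts and an intercept-only model. Per-gene counts of both libraries were compared with sampling noise by a chi-square statistic. Genes counted as detected had TPM of at least 1 in both libraries. Differences between the pools were log2 ratios of TPM, replicate 1 over replicate 2, after adding 0.1 to both. This pseudocount understates the ratios of low genes. A size rule counted genes with a mean expected count of at least 50 and a ratio of at least 2-fold. The top transcript of a gene was compared between the libraries for genes with at least 2 annotated transcripts and TPM of at least 10 in both.

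Gene lists, the rule for the genes named, the size rules and most alternatives were fixed before the data were examined. The 31 lists held 346 gene entries. They covered adult-type and embryonic globins, erythroid transcription factors and receptor, heme synthesis and iron uptake, red cell membrane and maturation, hepatoblast, adult hepatocyte function, coagulation and complement, cholangiocyte, hematopoietic stem and progenitor, macrophage, granulocyte, megakaryocyte and platelet, lymphoid, mast cell and basophil, endothelial, stellate and mesenchymal, mesothelial, heart, gut with pancreas and lung, neural and skeletal muscle, adrenal with gonad and kidney, cell cycle, imprinted, oncofetal RNA-binding and growth, hematopoietic niche factor, iron handling, immediate early and heat shock, hypoxia, abundant noncoding RNA and sex-linked genes. A total of 2 entries were not analysed here. For each list, the median of its members' mean TPM was placed among the medians of 10000 random lists of the same size drawn from all genes with TPM above 0 in either library. For the pools, the median log2 ratio over members at mean TPM of at least 0.1 was placed among 10000 random lists matched on mean TPM in 20 bins. These percentiles describe the libraries and are not tests of samples. Lists of skeletal muscle, heart only, eosinophil and antioxidant genes and the group of histone genes were added after the values had been seen.

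Globin genes here are the protein-coding genes with a symbol starting with Hba- or Hbb-. The genes named were all of these, Afp, Alb and the 10 most abundant genes that were neither spike-ins nor mitochondrially encoded. The 4 most abundant members of each list were also named, with members of lists for other organs at mean TPM of at least 1. The rule further took the sex-linked genes and the 5 genes with the largest ratio in each direction at a mean expected count of at least 100. It also took the 5 genes with the largest shift in the share of their top transcript. Outside this rule, Hamp, Cyp7a1, Cps1, Cyp2c29, Sds, G6pc, F9, Fos and Cd3e were named after their values were seen, as low members of their lists, as were Prg2, Prg3, Epx, Actc1, Acta1 and Ttn, and the genes of the added groups. Not every gene that the rule takes is given in the text.

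Alternatives covered the pseudocount, filters on low values, FPKM or expected counts in place of TPM, DESeq2 1.42.0 size factors, centring on the spike-ins, rescaling without globin, mitochondrial and spike-in genes, and each library alone. Removing genes shorter than 200 nt, using reads scaled by depth but not divided by effective length, and leaving muscle genes over 2-fold out of the muscle values were added after the data had been seen. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

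The scripts were tested on simulated data before use. Coefficients of variation of 0.05, 0.1 and 0.2 were recovered as 0.0503, 0.100 and 0.198. For the comparison of the pools over 13017 genes, 200 genes were changed in each simulation. The 2-fold rule took 1% of genes changed 1.5-fold, 93.5% of those changed 2.5-fold and 100% of those changed 4-fold. It also took between 6 and 8 unchanged genes. Every simulated gene varied independently with the same coefficient of variation, 0.0437. Fitted by abundance, the median in the data was 0.0561, or 0.129 without the filter on low counts. The number of unchanged genes taken is therefore no error rate for the real pools. Of 200 simulated lists with no shift, 4% lay outside the central 95% of random lists, against 100% of 200 lists with a shift of 0.2 in log2 ratio. These lists were all of the same size, drawn from the more abundant genes and given independent noise. The rates do not carry over to short lists, low genes or genes that vary together. For the lymphoid list, for example, the random lists spanned -0.44 to 0.41.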

Results

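Liver RNA of mouse embryos at embryonic day 12.5, when the organ is both a site of blood formation and a developing gland, was profiled in 2 libraries. The libraries came from separate pools of 120 embryos (replicate 1) and 88 embryos (replicate 2) and held 37.6 M and 34.7 M expected counts. With 1 group, the data describe the RNA of this tissue and how far the 2 pools differed. Values are mean TPM ± SD over both libraries (n = 2) unless said otherwise.

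The pools gave similar values for abundant genes. Hba-a2, the most abundant gene, had 106431 TPM in replicate 1 and 107445 TPM in replicate 2, and the hepatoblast marker Afp had 5312 and 5136 TPM. The erythroid transcription factor gene Nfe2 had 146 and 145 TPM. Over the 23508 genes with TPM above 0 in either library, Pearson's r across genes was 0.9949 (0.9944 to 0.9955 by bootstrap over genes) and Spearman's rho was 0.961. Of the 12843 genes at TPM of at least 1 in both libraries, 67.8% lay within 1.1-fold between the pools. The common biological coefficient of variation was 4.37% over 15607 genes. Fitted by abundance, its median over genes was 0.0561 as a fraction. The libraries were pools of embryos, so these values do not give the variation between embryos. The chi-square statistic averaged 3.83 per gene, where sampling noise alone gives about 1.

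**Figure D1:**
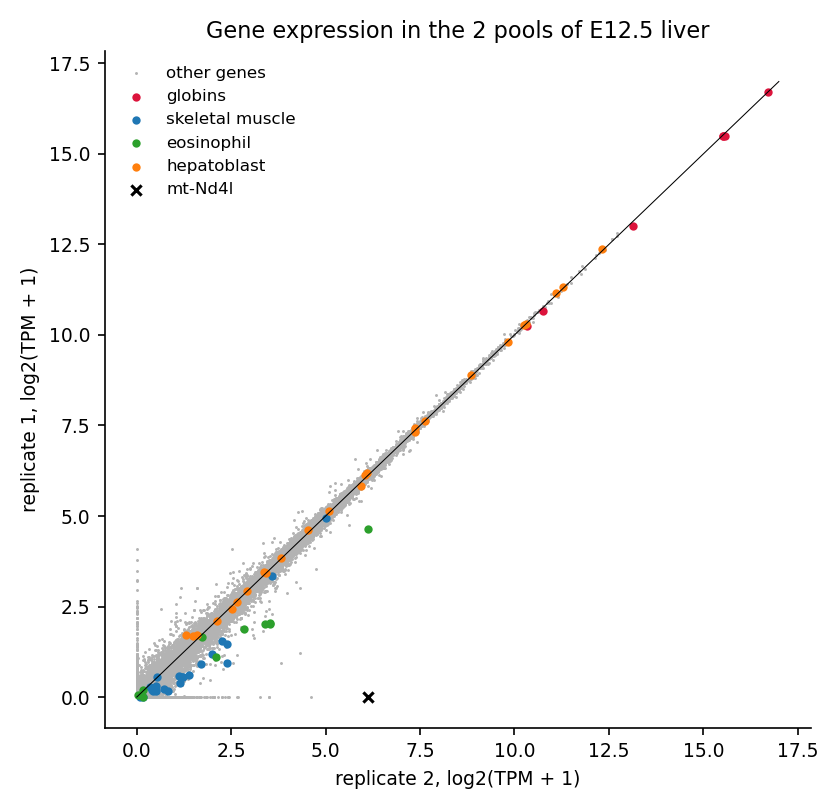
Gene expression in replicate 1 (vertical axis) against replicate 2 (horizontal axis), both as log2(TPM + 1), with each point a gene and the line marking equal values. Globin and hepatoblast genes lie along the line, while many skeletal muscle and eosinophil genes, groups added after the values had been seen, lie below it, and mt-Nd4l (cross) lies at 0 TPM in replicate 1 and 68.3 TPM in replicate 2.

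The 12843 detected genes comprised 11696 protein-coding genes, 497 long noncoding RNA genes, 430 pseudogenes, 143 genes of small RNA and other classes and 77 identifiers without an entry in the M21 annotation. A further 717 genes reached TPM of 1 in only one library, and 19828 genes had no reads in either. The abundance ranking was led by globins. Hba-a2, Hbb-bs, Hbb-bt, Hba-a1 and Hbb-y took the leading places. They were followed by Ftl1, which encodes the ferritin light chain, at 6961 ± 302 TPM (chromosome 7, 45457944 to 45459884). Next came Gm22133, a 109-nt gene annotated as a miRNA that lies within Ftl1 on the same strand (45458089 to 45458197), at 6759 ± 126 TPM. That value rested on 2156 and 1944 reads over an effective length of 10 nt, against 195447 and 170083 reads for Ftl1, and reads of these overlapping genes could be divided either way. The signal recognition particle RNA genes Rn7s1 and Rn7s2 both had 6308 ± 209 TPM, with 40844 and 40841 reads in replicate 1, so the split between these near-identical genes was uncertain. The histone gene Hist1h2ap completed the leading 10 at 5284 ± 105 TPM. Whether it shares reads with other histone cluster genes was not examined.

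Adult-type globin RNA far exceeded embryonic globin RNA. At the alpha locus on chromosome 11, the adult genes Hba-a2 (ENSMUSG00000069917.7, 32296489 to 32297298) and Hba-a1 (ENSMUSG00000069919.7, 32283511 to 32284465) had 106938 ± 717 and 46424 ± 768 TPM, and the embryonic gene Hba-x (ENSMUSG00000055609.4, 32276400 to 32278116) had 1682 ± 72.6 TPM. At the beta locus on chromosome 7, the adult genes Hbb-bs (ENSMUSG00000052305.5, 103826534 to 103828096) and Hbb-bt (ENSMUSG00000073940.3, 103812524 to 103813996) had 47310 ± 1580 and 46484 ± 353 TPM. The embryonic genes Hbb-y (ENSMUSG00000052187.3, 103851749 to 103853216) and Hbb-bh1 (ENSMUSG00000052217.5, 103841637 to 103843164) had 8594 ± 536 and 1247 ± 52.1 TPM, and Hbb-bh2 had 0.825 ± 0.516 TPM from 5 and 12 reads.

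Adult-type genes made up 98.9% ± 0.0359 of alpha-like globin TPM, 90.5% ± 0.336 of beta-like globin TPM and 95.5% ± 0.185 of both together (SD, n = 2). The embryonic share was thus 1.08% on the alpha side and 9.49% on the beta side, and it was the larger on the beta side in both libraries, at 9.25% against 1.06% in replicate 1 and 9.73% against 1.11% in replicate 2. Among embryonic beta-like genes, Hbb-y exceeded Hbb-bh1 by 6.89 ± 0.142 times. Alpha-like genes summed to 155044 ± 1557 TPM and beta-like genes to 103634 ± 2521 TPM. Hba-a2 exceeded Hba-a1 by 2.30 ± 0.0226 times, but the adult genes of each locus are near-identical pairs, so the split of shared reads was uncertain. Their summed TPM and the shares built on it are less open to that split but not free of it. The genes and their transcript models differ in length.

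**Figure D2:**
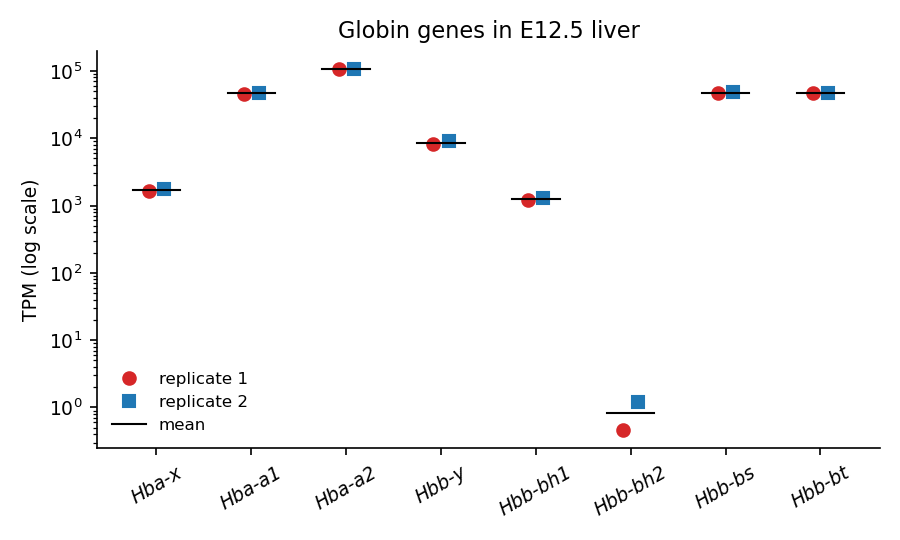
TPM of the globin genes on a log scale, with circles for replicate 1, squares for replicate 2 and bars for their mean. The adult genes lie between 45881 and 107445 TPM in the libraries, the embryonic genes Hbb-y, Hba-x and Hbb-bh1 between 1210 and 8973 TPM, and Hbb-bh2 near 1 TPM.

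A few gene classes took a large part of the TPM. The 8 globin genes held 25.9% ± 0.408 of all TPM, ribosomal protein genes (87 genes) 6.28% ± 0.121, spike-ins 5.39% ± 0.307 and the 37 mitochondrially encoded genes 1.89% ± 0.0187. The mitochondrial share leaves out reads assigned to pseudogene copies, so it depends on how such reads were split. For example, mt-Nd4l had 0 and 68.3 TPM in replicates 1 and 2. The pseudogene Gm10222, which holds nearly all of its sequence, had 323 and 243 TPM. The 10 most abundant genes held 28.7% ± 0.321. Because globin transcripts are short, their share of reads was smaller, at 10.8% ± 0.179 of expected counts. Genes shorter than 200 nt held 1.01% of TPM from 0.0225% of expected counts, so TPM values of such genes, Gm22133 among them, rested on very short effective lengths.

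Erythroid genes stood at high levels as a group. Of the 31 lists, 16 had a median above the central 95% of random lists, 5 below it and 10 inside it. Among genes of heme synthesis and iron uptake, all 11 members exceeded 100 TPM with a median of 465 TPM. They included the erythroid gene of the first enzyme of the pathway, Alas2, at 692.4 ± 20.99 TPM, Cpox at 553 ± 10.8 TPM and Alad at 547 ± 5.13 TPM. Red cell membrane and maturation genes had a median of 154 TPM over 14 members, with the anion exchanger gene Slc4a1 at 819 ± 34.6, Rhd at 416 ± 1.11 and Ermap at 286 ± 2.29 TPM. Erythroid transcription factors and receptor genes, all 10 detected, had a median of 112 TPM, led by Klf1 at 464 ± 22.1, Lmo2 at 166 ± 3.42, Nfe2 at 146 ± 0.247 and Gata1 at 132 ± 4.77 TPM. The adult-type and embryonic globin lists had medians of 46897 and 1682 TPM.

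Cell cycle genes were all detected, 20 of 20, with a median of 202 TPM. The ribonucleotide reductase gene Rrm2 had 470.5 ± 14.2 TPM, Pcna 309.8 ± 3.32, Mcm6 299.2 ± 0.679 and Cdk1 282 ± 10.8 TPM. Iron handling genes had a median of 62.3 TPM with 7 of 10 detected. Ferritin genes Ftl1 and Fth1 had 6961 ± 302 and 4837 ± 50.8 TPM and transferrin (Trf) 2530 ± 56.6 TPM, while Hamp, the gene of the iron hormone hepcidin, had 0.23 ± 0.17 TPM from 1 and 3 reads. Hypoxia genes, 9 of 9 detected, had a median of 59.7 TPM, led by Ldha at 1505 ± 70.1 TPM, Slc2a1 at 289 ± 1.06, Pgk1 at 229 ± 10.3 and Bnip3 at 70.8 ± 0.431 TPM.

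Fetal hepatocyte genes were high and most adult hepatocyte genes low. All 25 hepatoblast genes were detected, with a median of 58.2 TPM. Afp (ENSMUSG00000054932.3, chromosome 5, 90490737 to 90508907) had 5224 ± 124 TPM and its neighbour Alb (ENSMUSG00000029368.9, 90460897 to 90476602) 905 ± 10.8 TPM, an Afp to Alb ratio of 5.77 ± 0.206. Trf, Apoa2 and Apoa1, genes of secreted plasma proteins, had 2530, 2241 and 1257 TPM. In contrast, the adult hepatocyte function list had a median of 0.193 TPM, lower than 99% of random lists at a percentile of 0.775, with 9 of 22 members detected. Its members Glul, Ass1 and Gys2 had 88.7 ± 4.15, 51.6 ± 0.552 and 31.0 ± 1.39 TPM. Cyp7a1, the rate-limiting enzyme gene of bile acid synthesis, had 0.17 ± 0.0141 TPM, and the urea cycle gene Cps1 had 0.08 ± 0.0141 TPM. No reads were assigned to Cyp2c29, Sds or G6pc, which allows up to 0.047, 0.15 and 0.041 TPM in replicate 1. Coagulation and complement genes, by comparison, had a median of 62.7 TPM with 15 of 16 detected. Serpinc1 had 199 ± 4.45, Fga 166 ± 3.06, Fgg 152 ± 5.90 and Fgb 123 ± 2.19 TPM, while F9 had 0.485 ± 0.0354 TPM.

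Among other blood lineages, megakaryocyte and granulocyte genes were the most abundant. Megakaryocyte and platelet genes, all 10 detected, had a median of 31.7 TPM, with Pf4 at 618 ± 66.0, Ppbp at 147 ± 6.82, Itga2b at 74.8 ± 3.90 and Gp1bb at 39.2 ± 0.665 TPM. Granulocyte genes, all 12 detected, had a median of 23.3 TPM, with S100a8 at 256 ± 27.4, Mpo at 186 ± 4.47, S100a9 at 131 ± 26.7 and Ngp at 37.6 ± 3.20 TPM. Macrophage genes had a median of 8.54 TPM with 15 of 16 detected. Lyz2 had 107 ± 3.42 TPM, the iron exporter gene Slc40a1 74.3 ± 0.410, C1qb 46.8 ± 0.806 and C1qc 28.8 ± 0.601 TPM. Hematopoietic stem and progenitor genes, 16 of 16 detected, had a median of 6.88 TPM. Mllt3, Cd34, Meis1 and Myb had 78.3 ± 2.56, 23.9 ± 1.11, 21.5 ± 0.0566 and 20.1 ± 0.00707 TPM. Medians of the macrophage and progenitor lists lay inside the central 95% of random lists.

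Lymphoid and mast cell genes lay near the detection limit. The lymphoid list had a median of 0.075 TPM with 2 of 13 members detected, Cd79b at 4.12 ± 0.735 and Lck at 4.03 ± 0.636 TPM, followed by Vpreb1 at 0.47 ± 0.0283 TPM. Cd3e had no reads. The mast cell and basophil list had a median of 0.0575 TPM, and 1 of its 6 members was detected, Cpa3 at 3.38 ± 0.389 TPM.

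Of the supporting cell types, endothelial genes (15 of 15 detected) had a median of 15.3 TPM and stellate and mesenchymal genes (13 of 14) one of 18.1 TPM, both above the central 95% of random lists. Egfl7, Oit3, Eng and Clec1b had 98.3 ± 8.92, 30.3 ± 3.18, 29.5 ± 1.90 and 28.3 ± 0.488 TPM. The collagen genes Col3a1, Col1a1 and Col1a2 had 170 ± 0.643, 125 ± 10.8 and 78.7 ± 5.78 TPM, and Lum had 50.3 ± 3.62 TPM. Bile duct and surface layer genes were lower. Cholangiocyte genes had a median of 2.05 TPM with 6 of 7 detected, led by Krt7 at 5.24 ± 0.0566 and Krt19 at 4.70 ± 1.73 TPM. Mesothelial genes had a median of 2.53 TPM with 5 of 6 detected, led by Upk3b at 9.07 ± 0.0566 and Wt1 at 6.01 ± 0.410 TPM. Hematopoietic niche factor genes had a median of 8.66 TPM with 9 of 10 detected, with Igf2 at 316 ± 13.1, Cxcl12 at 50.4 ± 0.0990 and Kitl at 13.7 ± 0.785 TPM.

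Growth genes of fetal tissue were also present. Imprinted genes, 19 of 19 detected, had a median of 62.3 TPM, with Gnas at 486 ± 12.9, Dlk1 at 468 ± 7.91, Mest at 335 ± 5.26 and Igf2 at 316 ± 13.1 TPM. Oncofetal RNA-binding and growth genes, 8 of 8 detected, had a median of 19.2 TPM. Gpc3 had 241 ± 1.05 TPM, and Igf2bp1, Igf2bp2 and Igf2bp3 had 31.1 ± 2.91, 25.9 ± 0.679 and 24.4 ± 1.06 TPM. Immediate early and heat shock genes, which respond to handling and stress, had a median of 3.59 TPM, with Ier2 at 32.1 ± 0.537 and Fos at 1.24 ± 0.0283 TPM. Abundant noncoding RNA genes had a median of 67.8 TPM. Malat1 had 1865 ± 14.3 TPM, a value that depends on most of its reads having been assigned to a 485-nt transcript model. Gas5 had 487 ± 22.6, Rn7sk 133 ± 14.0 and Rpph1 67.8 ± 15.1 TPM. Sex-linked genes had a median of 9.57 TPM, and all 5 were detected in both libraries, and the labels give both pools as mixed in sex.

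Markers of neighbouring organs were mostly low. The heart list had a median of 1.41 TPM, with Myl7 at 19.2 ± 0.424, Tnnt2 at 2.12 ± 1.11, Tnni3 at 1.46 ± 0.00707 and Nppa at 1.41 ± 0.410 TPM. The gut, pancreas and lung list had a median of 0.015 TPM, with Barx1, a stomach mesenchyme gene, at 6.51 ± 0.438 TPM. The neural and skeletal muscle list had a median of 0.505 TPM with Myog at 2.59 ± 2.35 TPM, and the adrenal, gonad and kidney list had a median of 0.05 TPM with no member at 1 TPM.

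**Figure D3:**
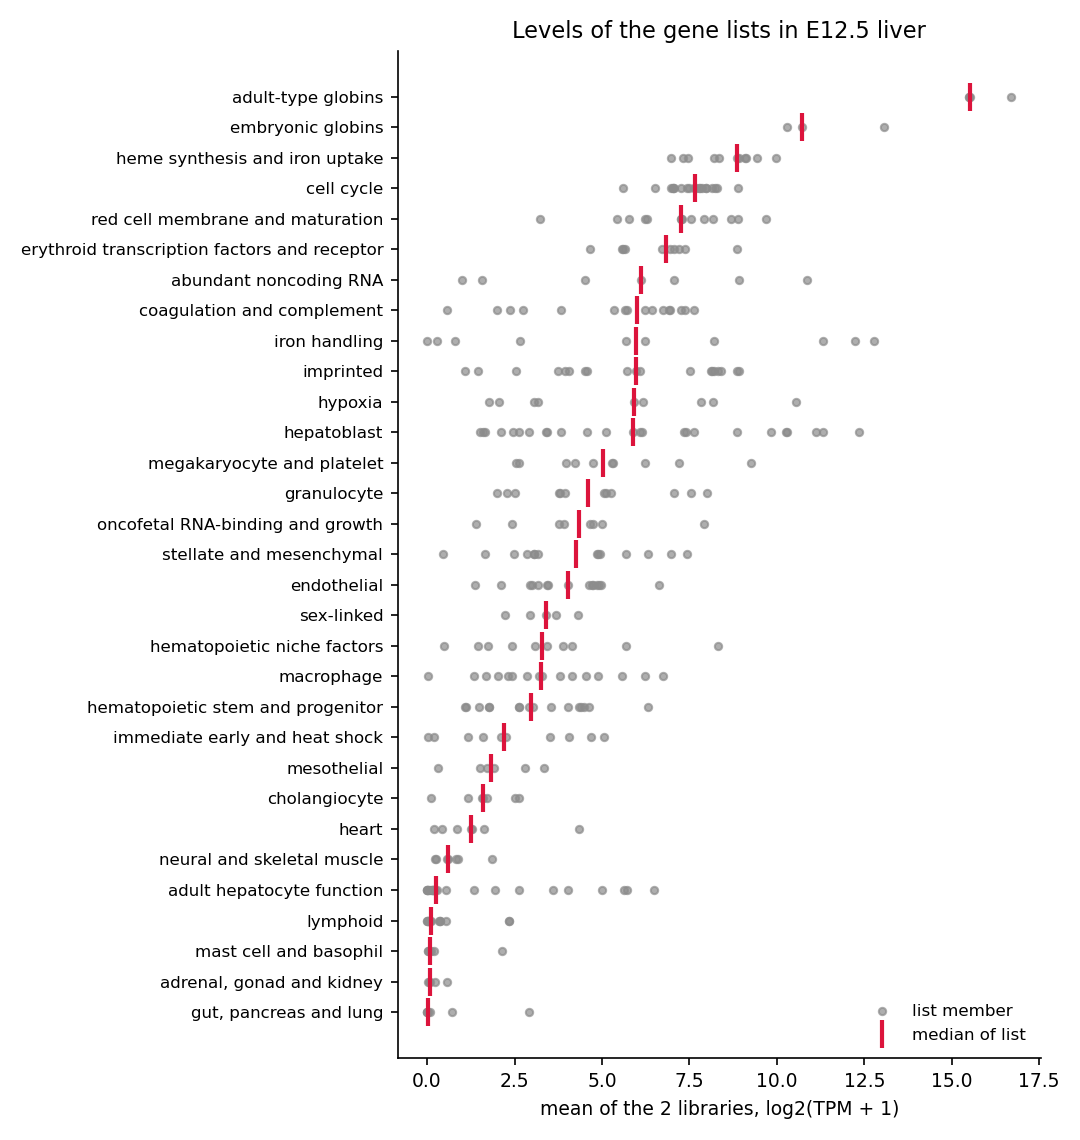
Mean TPM of every member (grey points) and the median (red bar) of each of the 31 gene lists, as log2(TPM + 1), ordered by median. Globin, heme synthesis, cell cycle and red cell lists lie at the top and lists of lymphoid cells, mast cells and other organs at the bottom.

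The pools were next compared by gene list. Granulocyte genes were lower in replicate 1, with a median log2 ratio (replicate 1 over replicate 2) of -0.22 and 10 of 12 members lower. S100a9 had 113 TPM in replicate 1 and 150 TPM in replicate 2, a fold of 1.34 (1.247 to 1.43) in favour of replicate 2, and S100a8 had 237 and 275 TPM. Megakaryocyte and platelet genes were higher in replicate 1, with a median of 0.14 and 9 of 10 members higher. Pf4 had 664 and 571 TPM, a fold of 1.16 (1.13 to 1.20) in favour of replicate 1. Stellate and mesenchymal genes had a median of -0.13, or -0.01 when centred on the spike-ins, with 8 of 14 lower and 6 higher in replicate 1. Col1a1 was lower at 118 against 133 TPM, and Lum was higher at 52.8 against 47.7 TPM.

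In all, 11 of the 31 lists lay outside the central 95% of matched random lists, where 1.55 would if the genes within a list varied independently. Genes of a list that vary together put it outside more often, so the excess is no measure of chance. Abundant noncoding RNA genes had a median log2 ratio of 0.21, with Rpph1 at 78.4 TPM in replicate 1 and 57.1 TPM in replicate 2. The heart list had a median of -0.36, with Tnnt2 at 1.33 and 2.90 TPM but Myl7 at 19.5 and 18.9 TPM. It lay at the edge of its random lists, and inside them by TMM, DESeq2 or a pseudocount of 1. The neural and skeletal muscle list had a median of 0.58, inside its random lists with a pseudocount of 1, and its members split. The muscle regulators Myog and Myod1 were lower in replicate 1, at 0.93 against 4.25 TPM and 0.31 against 1.23 TPM, while the neuronal gene Tubb3 had 0.66 and 0.35 TPM. Sex-linked genes had a median of -0.26. The 4 Y-linked genes, Ddx3y, Eif2s3y, Uty and Kdm5d, were lower in replicate 1 with a summed ratio of 0.799 (0.762 to 0.838), and Xist, expressed from the inactive X chromosome of females, was higher in replicate 1 at 10.6 against 8.51 TPM.

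Small shifts appeared in 4 further lists. Medians were -0.09 for embryonic globins, -0.04 for heme synthesis and iron uptake, -0.07 for red cell membrane and maturation (14 of 14 lower) and -0.03 for imprinted genes, or 0.03, 0.07, 0.05 and 0.08 when centred on the spike-ins, so their direction depends on the scaling. That centring moves the median of all genes by 0.12 in log2 ratio, as endogenous over spike-in TPM was 1.09 times higher in replicate 1. The same 11 lists then lay outside their random lists. This is no separate check, since the centring moves a list and its random lists nearly alike. The other 20 lists lay inside the central 95%, with medians from -0.43 (mast cell and basophil) to 0.25 (lymphoid). Each pool was 1 library, so these differences had no replicate check.

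**Figure D4:**
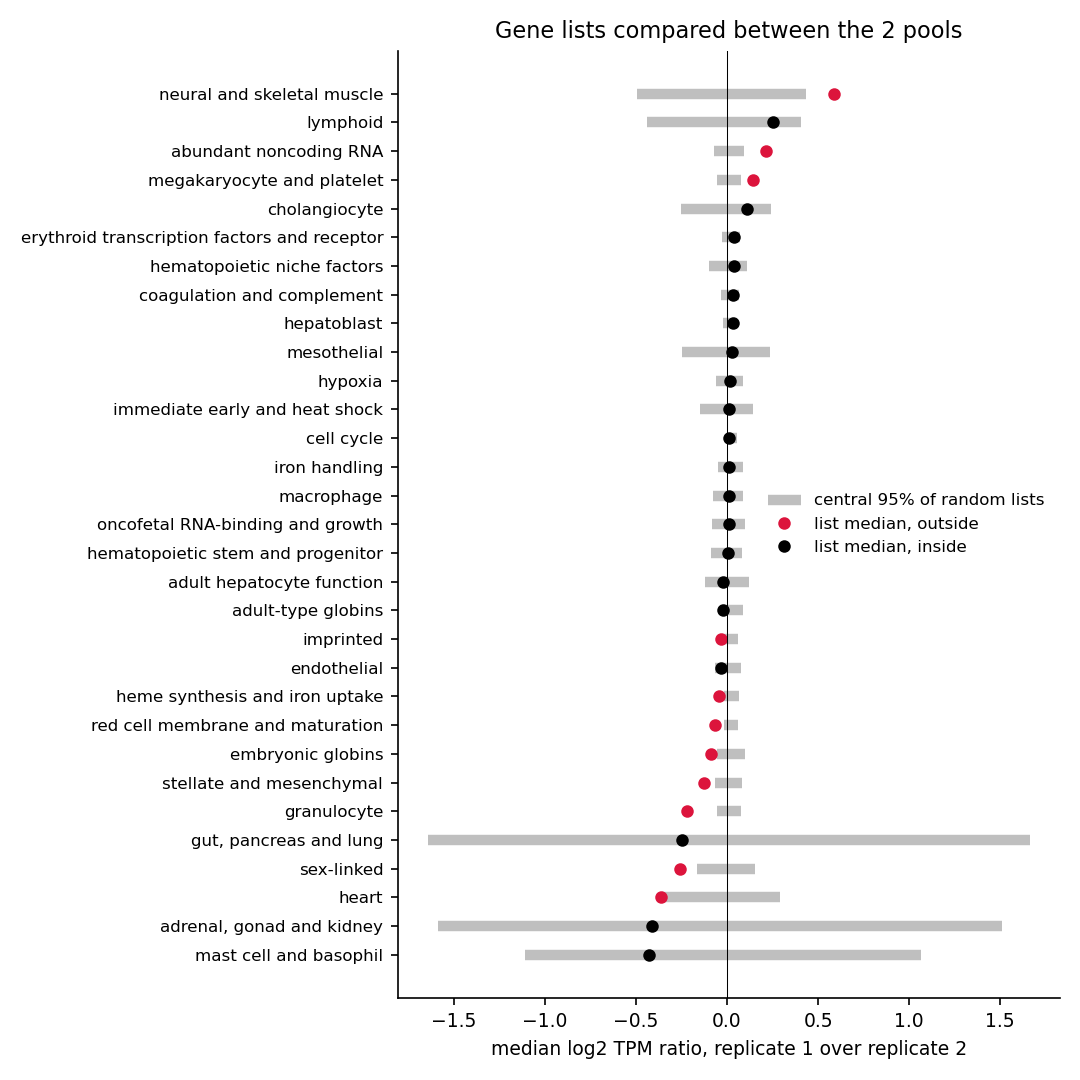
Median log2 TPM ratio, replicate 1 over replicate 2, of the 31 lists (points), with the central 95% of 10000 matched random lists as grey bars. The 11 red points lie outside the bars, and those of embryonic globins, heme synthesis, red cell membrane and imprinted genes become positive when ratios are centred on the spike-ins.

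Single genes were compared last. Among 13017 genes with a mean expected count of at least 50, 47 differed over 2-fold, 40 of them lower and 7 higher in replicate 1. This depends on the limit, with 157 lower and 121 higher at a mean expected count of at least 10, and 2 and 0 at 500. Among the 5 genes lowest in replicate 1 at a mean expected count of at least 100 were the eosinophil-associated ribonuclease genes Ear1, Ear2 and Ear6 on chromosome 14, at 3.05, 3.07 and 3.16 TPM in replicate 1 and 10.5, 9.59 and 10.4 TPM in replicate 2. Ear1 differed by 3.44-fold (2.54 to 4.67), and the split of reads among these paralogs was uncertain. The muscle regulator Myog (chromosome 1, 134289989 to 134292548) was lower in replicate 1 by 4.57-fold (3.23 to 6.57), from 41 and 173 reads. The fifth, mt-Nd4l (chromosome M, 9877 to 10173), was listed at 0 in replicate 1 and at 68.3 TPM in replicate 2. Nearly all of its sequence also occurs in a pseudogene, so its own level was uncertain.

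Of the 47, 6 are in a list of eosinophil genes and 8 in lists of skeletal muscle or heart genes, lists drawn up in part after the values were seen, 33 are in none of these, and 10 are pseudogenes. A few are given here outside the rule for named genes. The eosinophil granule genes Prg2, Prg3 and Epx had 24.1, 2.70 and 1.17 TPM in replicate 1 and 68.6, 6.14 and 3.32 TPM in replicate 2. The sarcomere genes Actc1, Acta1 and Ttn had 7.98, 1.74 and 0.46 TPM against 17.7, 4.25 and 1.34 TPM. The 5 genes highest in replicate 1 at a mean expected count of at least 100, some of them under 2-fold, were the pseudogenes Gm10182, Gm10171 and Gm10254, with Gm28042 and Hand1. Gm10182 had 7.70 and 3.28 TPM, a fold of 2.35 (1.85 to 3.02). Hand1, a transcription factor gene of heart and mesenchyme, had 2.58 and 1.37 TPM, a fold of 1.88 (1.41 to 2.56). Gm28042 had 1.88 and 0.82 TPM but 112 and 111 reads, so its difference came from the effective lengths. In reads scaled by depth alone, an alternative chosen after the data were seen, 40 genes differed over 2-fold, and 35 of the 47 were among them, 31 lower and 4 higher in replicate 1.

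The leading transcript of a gene was the same in both pools for most genes. Among 5275 genes with several annotated transcripts, 5044 kept their top transcript, 95.6% (exact 95% interval 95.03% to 96.16%). This binomial interval treats genes as independent, and it covers neither counting error nor the spread between pools. The share of the top transcript moved by a median of 2.11 percentage points, and by at least 20 points in 41 genes. Ftl1-201 held 98.6% ± 0.0921 of Ftl1, Hba-a2-201 held 99.998% ± 0.00129 of Hba-a2, and Alas2-201 held 67.2% ± 1.66 of Alas2.

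The largest shifts were in Fxyd5, Tmem40, Specc1l, Ak4 and Mdm1. The transcript Fxyd5-203 held 48.8% of Fxyd5 in replicate 1 and 1.45% in replicate 2, from 205 and 5 reads. Tmem40-203 held 45.1% and 0%, Specc1l-202 57.6% and 100%, Ak4-201 75.8% and 38.9%, and Mdm1-201 58.9% and 22.2%. The gene TPM of each differed far less, as in Tmem40, with 27.4 and 24.5 TPM. Some abundant genes were dominated by short models. The transcripts with the largest shares of Hba-a1 and Hbb-bs, 494 and 549 nt long, are annotated as retained introns and held 80.7% ± 0.140 and 67.2% ± 0.413. For Malat1, a 485-nt model held 99.3% ± 0.0150 of TPM and 89.4% and 89.6% of reads, against 0.656% ± 0.0105 of TPM for the 6983-nt transcript. Shares of transcripts that overlap are estimates of how reads were split, and the gene TPM of Hba-a1, Hbb-bs and Malat1 depends on that split, because the same reads give a higher TPM on a shorter model.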

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

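No test bears on the values in this part. The tRNA entries of the gene tables, which enter none of the comparisons above, held 53.3 expected counts in replicate 1 and 44 in replicate 2 over 26248 entries, above the 3 counts that a total of 0 allows. Per the labels the RNA had a size range above 200, so these counts are no measure of tRNA levels. The values are given without an explanation.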

How the results depend on the processing

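The limits and alternatives were chosen before the data were examined, apart from removing genes shorter than 200 nt, using reads scaled by depth alone and leaving out muscle genes over 2-fold. No paired analysis was possible because there is 1 group. Leaving out a library left no ratio between the pools, and counts of detected genes and lists stayed within 1.5 times under each library alone, as did the 2-fold counts under edgeR TMM, DESeq2 and reads scaled by depth alone. Lists above the central 95% numbered 14 after rescaling, which leaves out both globin lists, and 16 in each other alternative. With replicate 1 alone the median TPM was 0.08 for adrenal, gonad and kidney (0.05 with both) and 0.03 for gut, pancreas and lung (0.015), and with replicate 2 alone the latter was 0. The cause was not tested unless it is stated.

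Pearson's r moved to 0.9817 with a pseudocount of 0.1 and to 0.9963 for genes at TPM of at least 1, where Spearman's rho was 0.9947, since low genes weigh more or are left out. By expected counts, which are not divided by length, the adult-type share was 98.5% of alpha-like and 94.9% of all globins. On the same scale the class shares were 10.8% for globins, 1.21% for mitochondrial genes, 3.15% for ribosomal protein genes, 3.06% for spike-ins, 11.5% for the 10 most abundant genes and 0.0225% for genes shorter than 200 nt. Without the latter genes, mitochondrial genes held 1.91% and the 10 most abundant 28.3%. Spike-in centring turned the log2 ratios of embryonic globins to 0.0280, heme synthesis to 0.0740, red cell membrane to 0.0510 and imprinted genes to 0.0849. Of the 11 lists outside matched random lists it turned no other, and TMM, DESeq2 and rescaling without globin, mitochondrial and spike-in genes turned none. Among the other lists, spike-in centring turned adult-type globins (0.0915), adult hepatocyte (0.0941) and endothelial genes (0.0813) positive. That rescaling turned stem and progenitor, macrophage, cell cycle, oncofetal, iron handling, immediate early and hypoxia genes slightly negative. Lists outside matched random lists numbered 10 under TMM and DESeq2, which lost heart, and 9 with a pseudocount of 1, which lost heart and neural and skeletal muscle, against 11. TMM, DESeq2, spike-in centring and the rescaling move a list and its random lists nearly alike. These scalings could therefore hardly change the number of lists outside.

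Genes over 2-fold numbered 121 higher and 157 lower in replicate 1 at a mean expected count of at least 10, and 0 and 2 at 500, so the count depends on this limit. The top transcript was shared by 91.6% of genes at TPM of at least 1, 97.2% at TPM of at least 50 and 99.4% where each library's top transcript held at least 50% of its TPM, a condition that leaves little room for another outcome.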

Other observations

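The groups in this part were chosen after the values had been seen, as were the tests of heart cells, of Ear paralogs and of all granulocytes and the skeletal muscle values without genes past 2-fold, while the skeletal muscle, counting error and shared copy tests were set down before their own values were computed. Of 67 histone cluster genes, 52 had TPM of at least 1 and 5 had TPM of at least 100 in both libraries, and together they held 0.699% ± 0.00161 of TPM (SD, n = 2), most of it from the single gene Hist1h2ap at 5284 ± 105 TPM. It was followed by Hist1h4d at 400.5 ± 15.0, Hist1h2ae at 198 ± 7.07 and Hist1h3i at 148 ± 11.2 TPM. How shared reads were split among histone genes was not examined, so the values of single histone genes are uncertain. The median log2 ratio of histone genes, replicate 1 over replicate 2, was 0.13 over 50 genes, with an SD over genes of 0.41.

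Among antioxidant enzyme genes, Gpx1 had 5199 ± 21.4 TPM, Prdx2 1625 ± 26.3, Sod1 1105 ± 0.544, Prdx1 818 ± 44.0 and Cat 115 ± 6.60 TPM. The median log2 ratio of the 8 genes between the pools was 0.02, inside the central 95% of matched random lists. The added lists of skeletal muscle, heart only and eosinophil genes had medians of -1.20, -0.46 and -1.47 over 20, 10 and 8 genes. Myog and Myod1 of the skeletal muscle list are also in the fixed neural and skeletal muscle list, and no eosinophil gene is in a fixed list.

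Striated muscle genes were lower in replicate 1, with Myog at 0.93 TPM against 4.25 TPM in replicate 2. For 10 further skeletal muscle genes, kept by a limit on mean reads, the exact 95% interval of the summed read ratio ended at 0.731. It ended at 0.814 without Neb and Myh3, which are among the 47 genes over 2-fold. This argues against counting error only as far as reads are independent molecules, which PCR reads are not. A gene could also pass the limit mainly through replicate 2, as did Cdh15 with 14 and 52 reads. All 10 were lower in replicate 1 with a median log2 ratio of -0.88 (-0.72 without those 2), so more skeletal muscle tissue in the pool of replicate 2 is a hypothesis, which the most abundant of them, Mylpf at 29.7 and 31.0 TPM and Tnni1 at 9.08 and 11.01 TPM, hardly follow. For 8 heart genes, 4 of which the fixed heart list also holds, the median of -0.38 lay between the bounds set for and against heart cells, with Myl7 at 19.5 and 18.9 TPM, so heart tissue stays open. These tests concern tissue of other organs carried into a pool, and no biological explanation of the difference was tested, as both pools belong to 1 group.

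Eosinophil granule genes were lower in replicate 1 as well, with Prg2, the most abundant, at 24.1 and 68.6 TPM. Prg2 and Epx, which are not Ear genes, had a summed read ratio of 0.354 (0.323 to 0.387). The difference was thus not confined to the Ear paralogs. Both genes were already known to be over 2-fold lower in replicate 1. A low ratio was therefore certain, and it decides nothing about reads shared between the Ear paralogs. Whether such sharing accounts for the Ear values was not tested. The granulocyte list had a median of -0.22, with 10 of 12 members lower in replicate 1, against -1.50 for Prg2, -1.43 for Epx and -1.16 for Prg3. A larger share of all granulocytes in replicate 2 thus failed the test set for it. The values were known when that test was set, so it decides nothing, and such a share as part of the cause stays open. The criterion of that test was revised after its first form, which also asked every eosinophil gene to lie below the granulocyte median, gave no decision because Siglecf had a log2 ratio of -0.10. More cells of the eosinophil lineage in replicate 2 stay an untested hypothesis, which Siglecf at 2.15 and 2.31 TPM does not follow.

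The gene mt-Nd4l had 0 reads in replicate 1 and 394 in replicate 2. Of its 198 windows of 100 bases, 98.5% also occur in Gm10222, an unprocessed pseudogene on chromosome 1 (24612407 to 24612700), which had 1982 and 1379 reads. The summed reads of both were 1982 and 1773, a ratio of 1.03 after scaling by depth, which is consistent with reads of 1 source being assigned to different copies in the 2 libraries. No biological explanation was tested.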
